A study of Escherichia coli with 6 samples.

How the data were processed

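Escherichia coli K-12 MG1655 (DSM498) cells were irradiated with a blue laser, and their total RNA was compared with that of unirradiated cells on 6 custom Agilent arrays with 2 colours. Per the labels' protocols, exponential-phase cells from LB medium were washed into isotonic saline and irradiated at 448 nm with 62 W/cm2. Exposures lasted 5 s, a fluence of 310 J/cm2, and 20 s, a fluence of 1240 J/cm2. They were then kept at room temperature for 60 min before they were pelleted. RNA was extracted with a column kit, treated with DNase and labelled directly with a ULS dye kit. Each irradiation time had 3 arrays, which the labels call biological replicates. Unirradiated RNA carried Cy3 and irradiated RNA carried Cy5 on every array. With 0 dye swaps, a bias of a probe towards 1 dye cannot be separated from an effect of irradiation.

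The arrays were read with Agilent Feature Extraction 10.7.3.1, per the submitters' processing notes. The authors deposited a table of normalized log ratios, taken here as log2, with 1 row per probe and 1 column per array. Background correction, the normalization method and filters are not given in the sources used here. The authors also deposited a table of 15350 spots, taken here as the scanner software's log10 ratios, in which each array's median was 0. Between 22.8% and 31.8% of the spots of an array held an exact 0. The spot table has no probe names, so its spots could not be tied to coding sequences.

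The base of the logarithm is not written in either table. The 150 probes with the strongest values were multiplied by several factors and matched to their nearest spots across the 6 arrays. The median distance, relative to the size of the profile, was 0.0971 at the factor that turns log2 into log10 (0.301) and 0.0952 at 0.35. It was 0.106 at the factor for natural logarithms (0.434) and 0.271 with no factor. An equal base in both tables was therefore a poor match, but natural logarithms in the normalized table were only slightly worse than log2, so every fold given here rests on log2. The match with the sign turned gave 0.106, so this match does not settle the direction. The direction is likely irradiated over unirradiated, on the basis of the dyes and titles in the labels and of the table's form text, which asks for test over reference. Higher and lower are used in that sense throughout.

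The normalized table held 4483 probes. Of these, 4242 each named a different coding sequence by an ID made of a genome record, a protein accession and a running number. The other 241 were control probes, which were left out of the tests of coding sequences and fitted on their own. A protein accession stood in 4069 of the IDs and was missing in 173. The running numbers went from 1 to 4296. The reference gene table (assembly ASM584v2) matched 0 of the IDs, and the files do not pair the IDs with gene names. Coding sequences are therefore given without gene names, and the 50 gene lists, the genes to be reported whatever their result, and the rule of 8 rises and 8 falls per time, all fixed before the data were examined, could not be applied. In their place 4 IDs are printed: the largest rise at each time, the largest fall (the same coding sequence at both times) and the next largest fall at 5 s. Each had to pass the threshold and move the same way on all 3 arrays of the time. Other coding sequences are described in groups.

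Log ratios were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with 1 coefficient per irradiation time over all 6 arrays, which leaves 4 residual degrees of freedom. Each coefficient was tested against 0, and the contrast of 20 s minus 5 s was tested in the same fit. All tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over the 4242 coding sequences, with a threshold of 0.05. A test of a ratio against 0 uses the unirradiated cells only through the ratio. Where the arrays of a time share unirradiated RNA, which the labels do not say, it leaves out the spread of the controls. The number of arrays limits the precision, and the tables give no signal over background.

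Running numbers were used to find runs, which are stretches of at least 3 consecutive numbers that all passed the threshold in the same direction. Runs were added after the IDs proved to have no gene names. They assume that numbers follow the order along the genome record, as the numbering of such coding sequence files usually does. The number of runs was compared with 10000 shuffles of the calls over the coding sequences.

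The fit was tested on simulated data for the comparison at 20 s: 5 draws of 4242 coding sequences with the measured spreads, of which 50 in each draw were changed at each of 4 sizes. It recovered 77.6% of changes of 0.25 on the log2 scale, 99.6% of changes of 0.5, and 100% of changes of 1 and of 2. Of the calls, 6.06% were false on average. Ratios on the replicate 1 arrays were compressed unevenly in the data, as described below. These shares may therefore not carry over to the data, above all for small changes. The alternatives tried were median centring, quantile normalization and scaling by the median absolute deviation, a variance trend with robust moderation, a fit of each time alone, stricter thresholds, a replicate block, a test without moderation, each array left out in turn, and the spot table. Array weights and a fit without both replicate 1 arrays were added after the data were examined.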

Results

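The 6 arrays measured RNA of irradiated cells against RNA of unirradiated cells, with 3 arrays after 5 s of blue laser light and 3 after 20 s. The design asks which transcripts differ from unirradiated cells 1 h after each exposure and how the exposures differ. Values are log2 ratios of irradiated over unirradiated cells, as the authors normalized them, over 4242 coding sequences. Within a time, the correlation between arrays across coding sequences was 0.515 to 0.724 at 5 s and 0.815 to 0.905 at 20 s. Between times it was 0.245 to 0.349. The replicate 1 arrays stood apart. Their interquartile range was 0.0304 at 5 s and 0.0557 at 20 s, while the other 4 arrays lay between 0.201 and 0.266. Means over 3 arrays include these narrow arrays, so means of weak changes are smaller in size than on the other arrays of the time. SDs over 3 arrays include this difference too.

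**Figure D1:**
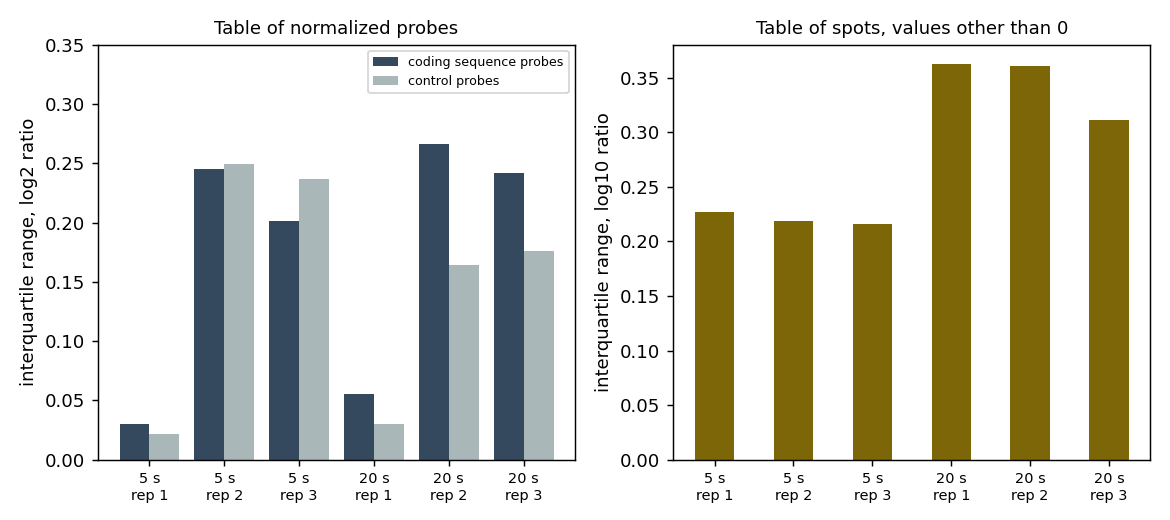
Interquartile range of the log ratios on each of the 6 arrays. The left panel shows coding sequence and control probes in the normalized table (log2 ratio), where the replicate 1 arrays reach 0.0304 and 0.0557 for coding sequences. The right panel shows spots other than 0 in the spot table (log10 ratio), where replicate 1 is not narrower than the other arrays of the same time.

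After 5 s, 40 coding sequences were higher and 32 were lower than in unirradiated cells, 1.70% of those tested. The largest rise was that of CP047127.1_cds_QHB66224.1_652, with a log2 ratio of 1.99 ± 0.19 (SD, n = 3), or 3.96-fold, and a limma adjusted p of 9.35e-06. Its neighbours in the numbering had values of -0.09 and -0.22 and did not pass the test. In all, 10 coding sequences were at least 2-fold higher, with means of 1.03 to 1.99, and 0 were at least 2-fold lower. This split depended on the scaling: under quantile normalization 14 were at least 2-fold higher and 7 at least 2-fold lower, and under scaling by the median absolute deviation 0 were called either way at that size. The largest fall was that of CP047127.1_cds_QHB67874.1_2440, at -0.87 ± 0.09 (SD, n = 3; adjusted p 9.74e-05), followed by CP047127.1_cds_QHB66110.1_528 at -0.73 ± 0.10 (SD, n = 3; adjusted p 0.0022). Under quantile normalization these were at -1.44 and -1.33 (limma adjusted p 0.000675 and 0.00306). That method gives all arrays the same distribution. Across coding sequences, the SD of an array was 0.101 to 0.227 at 5 s and 0.269 to 0.367 at 20 s. The method therefore widens large ratios at 5 s by construction, and its values there are no evidence of larger changes.

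The changes at 5 s included 5 runs of neighbouring coding sequences, of which 3 were higher and 2 lower. The calls shuffled over the coding sequences gave 0.0054 runs on average and at most 1 (permutation p = 1e-04, the smallest that 10000 shuffles can give). A run of 5 that holds CP047127.1_cds_QHB67874.1_2440 was lower, with a mean of -0.71 ± 0.07 (SD over 3 arrays). A run of 3 was lower at -0.44 ± 0.04. The 3 runs that were higher had 3 members each, with means of 0.89 ± 0.18, 0.57 ± 0.13 and 0.31 ± 0.07 (SD over 3 arrays). The count of 5 runs was 16 without 5 s replicate 1, 1 without 5 s replicate 2 or without 5 s replicate 3, and 3 without 20 s replicate 2.

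The count of 72 at 5 s depended on single arrays. It rose without a narrow replicate 1 array, to 556 without that of 5 s and 180 without that of 20 s. It fell to 22 without 5 s replicate 2 and to 30 without 5 s replicate 3. Without both replicate 1 arrays, a fit chosen after the data were examined, 843 (19.9%) passed at 5 s and 1389 (32.7%) at 20 s. The gap between 1.70% at 5 s and 25.8% at 20 s therefore depended in part on these arrays. In the main limma fit, 1020 coding sequences had an unadjusted p under 0.05 at 5 s, against 1481 at 20 s. Quantile normalization, which gives the 5 s arrays the same distribution as the wider 20 s arrays, gave 813. A test without variance moderation gave 0 at adjusted p under 0.05 and 224 at unadjusted p under 0.05.

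After 20 s, 515 coding sequences were higher and 579 were lower, 25.8% of those tested. Of these, 44 were at least 2-fold higher and 60 at least 2-fold lower. Under quantile normalization, which gives the 20 s arrays the same distribution as the narrower 5 s arrays, the counts at that size were 17 and 17. Under scaling by the median absolute deviation they were 6 and 5. The median ratio of the calls was 0.32 for those that were higher and -0.37 for those that were lower. These means include the narrow replicate 1 array, where weak ratios were smaller. The largest rise was that of CP047127.1_cds_QHB69497.1_4229, with 1.95 ± 0.16 (SD, n = 3), or 3.85-fold, and a limma adjusted p of 2.63e-07. The largest fall was again that of CP047127.1_cds_QHB67874.1_2440, at -2.21 ± 0.17 (SD, n = 3; adjusted p 7.89e-08), a 4.62-fold decrease. CP047127.1_cds_QHB66110.1_528 was at -1.37 ± 0.28 (SD, n = 3; adjusted p 1.50e-06).

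**Figure D2:**
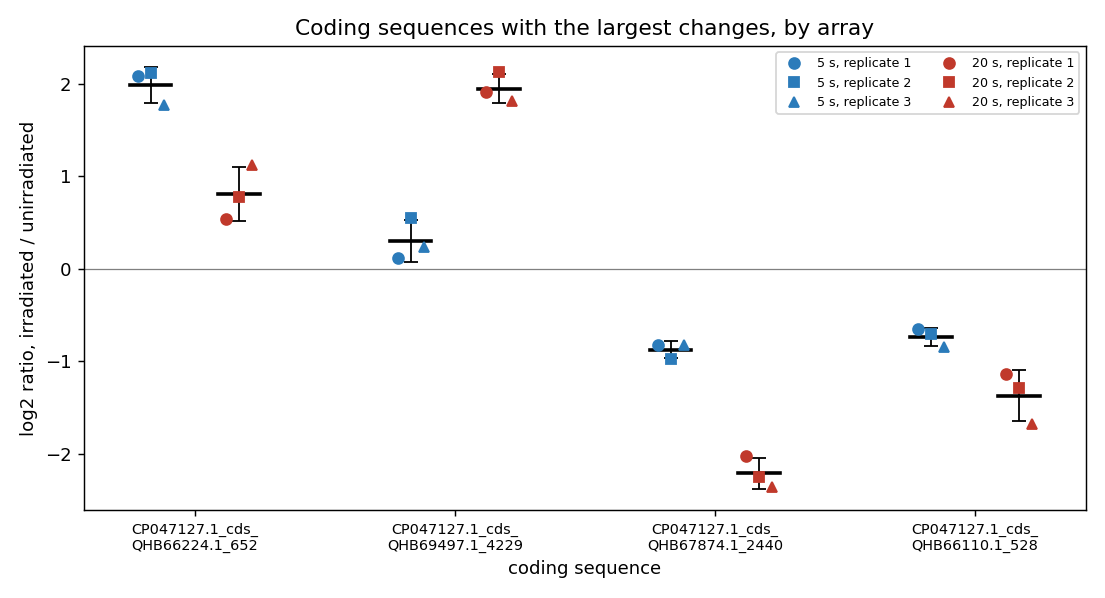
Log2 ratio of irradiated over unirradiated cells on each array for the 4 coding sequences given by ID, at 5 s (blue) and 20 s (red), with symbols for replicates, bars for the mean and error bars for the SD over 3 arrays. Every array shows the same sign for a given coding sequence, with means at 20 s from -2.21 to 1.95.

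Neighbouring coding sequences changed together at 20 s. There were 84 runs, 41 higher and 43 lower, which held 360 coding sequences or 32.9% of the calls. The count of runs was 39 without 20 s replicate 2, 44 without 20 s replicate 3 and 23 under scaling by the median absolute deviation. Shuffles of the 1094 calls of the main fit gave 15.6 runs on average and at most 31, against 84 (permutation p = 1e-04, the smallest possible). The other fits had fewer calls and were not shuffled, so their counts of runs cannot be set against these values. The longest run held 28 consecutive coding sequences, all higher, with a mean of 1.07 ± 0.11 (SD over 3 arrays), or 2.10-fold, and single means from 0.68 to 1.56. All 28 were above 0 on each of the 3 arrays at 20 s. At 5 s the same stretch had a mean of 0.21 ± 0.08 (SD over 3 arrays), with 4 of the 28 past the threshold. All 28 passed at 20 s when any 1 array was left out and under quantile normalization, but 2 of them passed under scaling by the median absolute deviation and 0 without variance moderation.

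Other runs that were higher at 20 s held 10 coding sequences with a mean of 0.80 ± 0.21, 8 with 0.83 ± 0.17 and 7 with 0.39 ± 0.06 (SD over 3 arrays). All members passed under 14 of 17 alternatives for the run of 10, under 6 for the run of 8 and under 2 for the run of 7. CP047127.1_cds_QHB69497.1_4229 lay in a run of 5 with a mean of 1.08 ± 0.21. Among the runs that were lower, a stretch of 9 had a mean of -0.85 ± 0.15 and another of 9 had -0.49 ± 0.29. All members of each passed under 11 of 17 alternatives. The run around CP047127.1_cds_QHB67874.1_2440 held 6 coding sequences at 20 s, with a mean of -1.43 ± 0.05 (SD over 3 arrays). A further run of 6 was at -0.59 ± 0.08.

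The count of 1094 at 20 s was 562 without 20 s replicate 2 and 643 without 20 s replicate 3, 576 with scaling by the median absolute deviation and 0 without variance moderation, where 600 had an unadjusted p under 0.05. The 241 control probes were fitted on their own, with p-values adjusted over these probes alone. Of them, 16 passed at 20 s, all higher, by up to 0.46. The control probes ranged from -1.45 to 0.46, and 193 of the 1094 coding sequences lay outside that range, 179 higher and 14 lower. The lower bound was set by a single probe, SC7.6. Without it the lowest control was at -0.18, and 724 lay outside, 545 of them lower. At 5 s, 26 of the 72 lay outside the range of all control probes and 38 without SC7.6, and the central 95% of the control probes (-0.27 to 0.23) was about as wide as that of the coding sequences (-0.25 to 0.28).

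**Figure D3:**
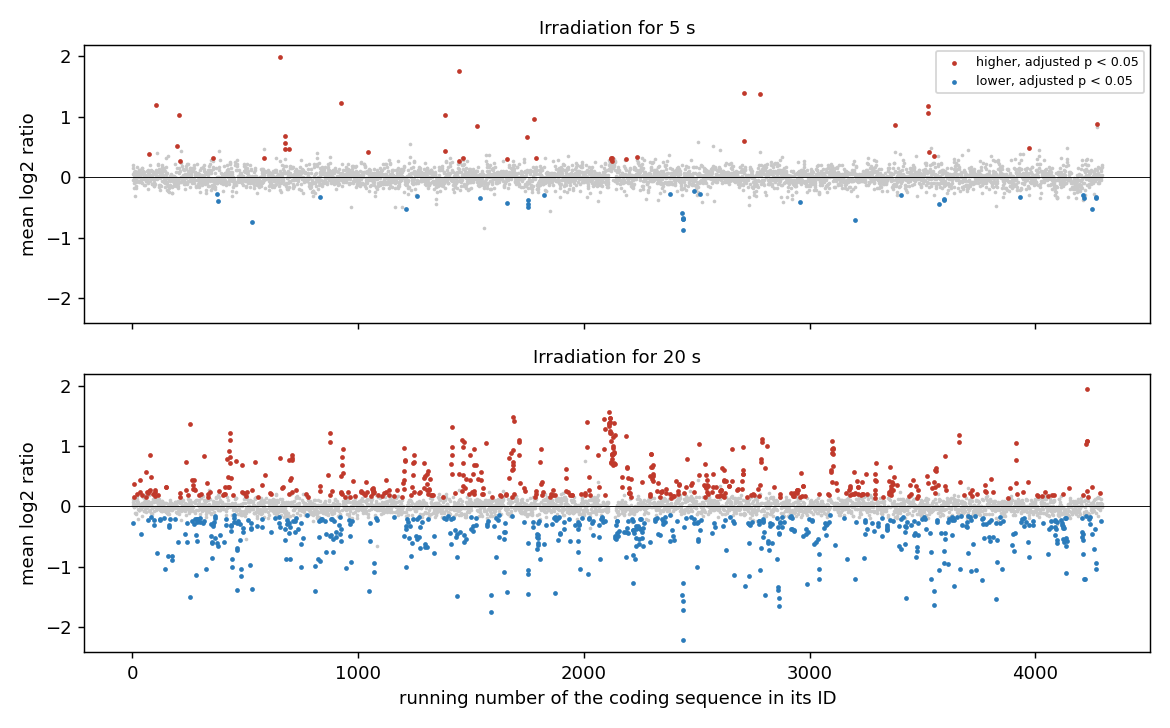
Mean log2 ratio of each coding sequence (3 arrays) against the running number in its ID, after 5 s (upper panel) and 20 s (lower panel). Red and blue points passed adjusted p under 0.05 as higher or lower (40 and 32 at 5 s, 515 and 579 at 20 s), grey points did not, and the stretch of 28 that were higher at 20 s stands out near the middle.

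The effects of both exposures were compared directly by the contrast of 20 s minus 5 s. It differed from 0 for 621 coding sequences, with 254 higher and 367 lower at 20 s than at 5 s. Of the 515 that were higher at 20 s, 245 were also higher than at 5 s, and of the 579 that were lower, 302 were also lower than at 5 s. In the run of 28, 27 passed this test. CP047127.1_cds_QHB69497.1_4229 was at 0.30 ± 0.23 (SD, n = 3) at 5 s and did not pass there (limma adjusted p 0.103). It passed there under 5 of 15 alternatives, among them quantile normalization (0.46, adjusted p 0.019) and the fit without 5 s replicate 1 (0.39, adjusted p 0.0306). Its difference was 1.65 ± 0.12 (SE; limma adjusted p 3.49e-05). CP047127.1_cds_QHB67874.1_2440 was lower at 20 s than at 5 s by a difference of -1.33 ± 0.09 (SE; limma adjusted p 3.49e-05). Scaling by the median absolute deviation lost this call, with a difference of -1.13 (limma adjusted p 0.709). Quantile normalization lost it too, with a difference of -0.22 (limma adjusted p 0.403). That method gives all arrays the same distribution, so the largest fall at both times receives nearly the same value at each (-1.44 and -1.66). It therefore cannot tell whether this fall differed between the times.

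The coding sequences raised most at 5 s went the other way. CP047127.1_cds_QHB66224.1_652 was at 0.81 ± 0.29 (SD, n = 3) after 20 s, and its difference was -1.18 ± 0.14 (SE; limma adjusted p 0.000337). All 10 coding sequences that were at least 2-fold higher at 5 s, a set chosen by its 5 s values, were lower at 20 s than at 5 s by this test. Their median was 1.21 at 5 s and 0.17 at 20 s, and 3 of them were still higher than in unirradiated cells at 20 s. The run of 3 with a mean of 0.57 at 5 s had a mean of -0.35 ± 0.20 (SD over 3 arrays) at 20 s, and all 3 members differed between the times. The run of 3 with a mean of 0.89 at 5 s was at 0.04 ± 0.11 at 20 s, again with a difference for all 3. The remaining run of 3 that was higher at 5 s, with a mean of 0.31, went up instead, to 0.77 ± 0.09 at 20 s, and all 3 members were higher at 20 s than at 5 s.

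The count of 621 was 405 and 376 without 5 s replicates 2 and 3, 382 without 20 s replicate 2, and 985 without both replicate 1 arrays, a fit chosen after the data were examined. Scaling by the median absolute deviation left 0, with 1028 at an unadjusted p under 0.05 in limma. That scaling uses a single factor per array, which a test given below argued against for 20 s replicate 1.

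Across coding sequences, which are not independent replicates, the mean ratios at 5 s and 20 s had a Pearson correlation of 0.355 and a Spearman correlation of 0.363, and 62.0% had the same sign. Of the coding sequences that passed, 13 were higher at both times, where independent lists would share 4.86, and 28 were lower at both times, against 4.37. Another 5 passed in opposite directions. Of the 41 that passed the same way at both times, 33 also differed between the times. With no dye swap, a dye bias common to all arrays cannot be separated from irradiation in any ratio against unirradiated cells, and a difference between the times does not remove it from either time.

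The labels do not say whether both times share unirradiated RNA. If replicates with the same number shared it fully, unchanged groups would give a correlation of 0.499 and 66.6% with the same sign (mean of 100 simulations). The observed 0.355 and 62.0% lay below these values, so neither shows more agreement than shared controls could give. The simulations gave 0 calls shared in the same direction. Unchanged groups give almost no calls, so this 0 cannot be set against the 41 seen. The covariance was 0.0160, against 0.00195 in these simulations, a difference of 0.0141. Array pairs with different numbers, which would not share controls in that case, had a mean covariance of 0.0154, and pairs with the same number 0.0174. Controls shared in another way may add to these values.

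**Figure D4:**
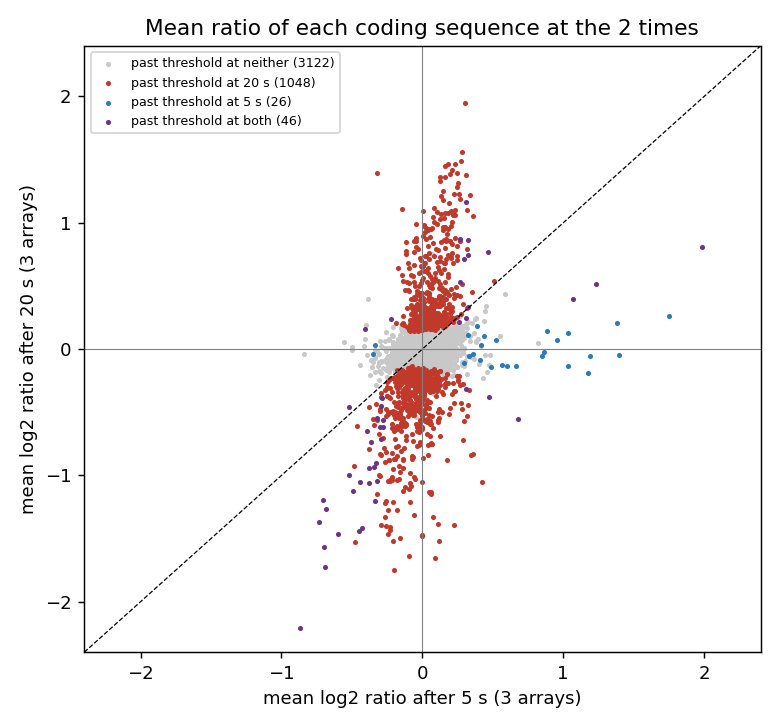
Mean log2 ratio after 20 s against that after 5 s for each of the 4242 coding sequences (3 arrays per time), coloured by the time at which it passed adjusted p under 0.05, with the dashed line marking equal ratios. Of them, 1048 passed at 20 s and not at 5 s, 26 at 5 s and not at 20 s, and 46 at both.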

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

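The tests of a weaker response, of a compression that differs from probe to probe and of a dye bias in the coding sequences raised at 5 s were chosen after the results were seen, as was the use of a sorting array in the test of a single scale factor. For shared noise between neighbours, a first test on deviations from the group mean (at most 0.243 on the 3 arrays) left it open, and the test given here was then added.

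The effects of the exposures differed for 621 coding sequences by the test of 20 s minus 5 s. In limma, the highest count from the other splits of the 6 arrays into 3 and 3 was 0, and 1 of the 10 splits, the real one, gave 621. With 10 splits, the share cannot fall under 0.05. A difference between the groups also marked 5 coding sequences that passed in opposite directions at the 2 times, 3 of them higher at 5 s and lower at 20 s.

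All 10 coding sequences that were at least 2-fold higher at 5 s were lower at 20 s than at 5 s. They were chosen by the 5 s values that enter this difference, so explanations were tested on 5 s arrays not used to choose. A dye bias common to all arrays would leave such an array no higher than the 20 s mean. With coding sequences chosen by a mean of at least 1 on a pair of 5 s arrays, the median difference of the remaining 5 s array from the 20 s mean was 0.613, 0.983 and 1.31, and 12 of 13, 10 of 10 and 10 of 10 differences were above 0. Nor were they merely chance highs of single arrays. On 5 s replicates 2 and 3, 13 coding sequences had a mean of at least 1. Their median on 5 s replicate 1, which was not used to select them, was 0.81, with all 13 above 0. If the 5 s arrays share unirradiated RNA, which the labels do not say, a chance low in it would appear on the held-out array too. This check cannot exclude that case. The call of the difference was lost for all 10 under scaling by the median absolute deviation, where the median difference grew from -1.18 to -2.57, and for 7 without variance moderation, where it stayed at -1.18. A dependence on the length of the exposure, or on how far cells had recovered after 60 min, stays open as a hypothesis and was not tested.

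The narrow spread of the replicate 1 arrays was weighed against 3 explanations. A weaker response of those cultures would leave the control probes as broad as on other arrays, but their interquartile range was 0.177 times that of replicates 2 and 3 at 20 s and 0.0894 times at 5 s. A single scale factor would shrink strong and weak ratios alike. To keep noise from diluting weak ratios, probes were sorted by one of the 20 s replicates 2 and 3, and replicate 1 was set against the other. The ratio was 2.68 and 2.76 times as high for probes beyond 1 as for those between 0.1 and 0.3 (bootstrap intervals 2.43 to 2.96 and 2.48 to 3.07), provided that replicates 2 and 3 share no noise. A compression in the authors' processing that differs from probe to probe is a candidate explanation: over 279 probes the compression at 5 s and at 20 s had a rank correlation of 0.616, against at most 0.435 in simulations with a single factor per array and noise that differs between probes. The simulations did not include a compression that depends on the size of the ratio, so they cannot tell it apart. Given the size of the change, the rank correlation was 0.511. Which step made the compression is open, since no intensities were used.

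That neighbouring coding sequences changed together at 20 s was weighed against noise and dye bias. Noise on single arrays would not tie a coding sequence on one array to its neighbour on another. The lowest of these correlations over 6 ordered pairs of arrays was 0.357. If the 20 s arrays share unirradiated RNA, which the labels do not say, chance shifts of neighbours in it would appear on every array. This check cannot exclude that case. A dye bias shared by neighbours and equal at both times would cancel in 20 s minus 5 s. There the neighbour correlation was 0.433, against 0.428 for the 20 s means. A bias that differs between the times would not cancel, so this test cannot exclude it. Joint transcription of neighbouring genes remains open as a hypothesis, since the files give no operons.

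Among the control probes, outside the main measurement, 16 passed at 20 s in the fit of the control probes alone. They included all 13 copies of the control CC_5, with a mean of 0.42 ± 0.18 (SD over 3 arrays) at 20 s and 0.17 ± 0.14 at 5 s. The other 3 lay between 0.20 and 0.34.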

How the results depend on the processing

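Array weights and the fit without both replicate 1 arrays were chosen after the data were examined, as were all counts of runs, the 2-fold counts under other scalings and the control range without SC7.6. The cause of the moves given here was not tested, except where fewer arrays or a stricter threshold make it plain. With each array left out in turn, the count at 5 s (72) lay between 22 and 556, at 20 s (1094) between 562 and 1280, for the difference (621) between 376 and 891, and the correlation of both times (0.355) between 0.326 and 0.367. At 5 s the count was 813 with quantile normalization, 405 with a variance trend and robust moderation, 148 with the arrays of that time alone, 770 with array weights and 843 without both replicate 1 arrays. At 2-fold or more it was 10, at adjusted p under 0.01 it was 33, and without variance moderation it was 0. Scaling by the median absolute deviation gave 96, of which 6 were among the 72. At 20 s the count was 576 with that scaling, 104 at 2-fold or more, 662 at adjusted p under 0.01, 0 without moderation and 1389 without both replicate 1 arrays. For the difference it was 0 with that scaling, 941 with trend and robust moderation, 67 at 2-fold or more, 353 at adjusted p under 0.01, 143 without moderation and 985 without both replicate 1 arrays. In the spot table, 9470 spots without a 0 on any array took the place of coding sequences. There 1640 spots passed at 5 s (17.3%, with 741 higher and 899 lower), 4639 at 20 s (49.0%) and 2550 for the difference (26.9%). The correlation was 0.438. The 15350 spots outnumber the 4483 probes, so a probe can stand in several spots. These counts are therefore not counts of coding sequences. With quantile normalization the correlation was 0.398.

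A fit with the replicate number as a block gave 379 calls at 5 s, 1187 at 20 s and 676 for the difference. Deviations of arrays with the same number correlated at 0.232, 0.0777 and 0.0678 for numbers 1, 2 and 3, and 3 of the 6 arrays correlated best with their own number, so the numbers were not taken to pair the arrays.

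The 4 coding sequences given by ID kept their direction at each time under all alternatives run on the normalized table. CP047127.1_cds_QHB69497.1_4229 had no call at 5 s. The other calls against unirradiated cells were lost without variance moderation, with equal ratios, and under scaling by the median absolute deviation, with larger ones (1.99 became 4.93 for CP047127.1_cds_QHB66224.1_652 at 5 s, and -0.87 became -2.01 for CP047127.1_cds_QHB67874.1_2440). The difference between times for CP047127.1_cds_QHB66110.1_528 turned to 0.39 (adjusted p 0.271) under quantile normalization, and its adjusted p ranged from 0.000498 to 0.917 over the alternatives. Runs numbered 0 to 32 at 5 s and 0 to 108 at 20 s. Averaging over probes and a filter on missing values changed nothing, with 1 probe per coding sequence and no missing values. A filter on dim probes and the alternatives for gene lists were not run, since the normalized table holds no intensities and no gene names. Signal over background is unknown, so limits for weak probes could not be set.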

Other observations

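At 20 s a run of 5 coding sequences that were higher, with a mean of 0.87 ± 0.17 (SD over 3 arrays), was followed directly in the numbering by a run of 5 that were lower, at -0.58 ± 0.05. At 5 s these stretches were at 0.17 ± 0.09 and -0.09 ± 0.07, with 0 members past the threshold, and 4 of the first 5 and all 5 of the second differed between the times. It was the single such pair among the 84 runs.

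Coding sequences without a protein accession passed less often at 20 s. Of 173, 21 passed (12.1%; 11 higher, 10 lower), against 1073 of 4069 with an accession (26.4%; Fisher's exact test, two-sided p 1.11e-05, adjusted 2.22e-05 over 2 tests). At 5 s the shares were 1.73% and 1.70% (p 0.769). Fisher's test treats coding sequences as independent, which the runs show they were not.

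The control probe SC7.6 had the most extreme mean of the control probes, -1.45 at 20 s and -0.79 at 5 s, and was below 0 on all 6 arrays (adjusted p 0.0534 and 0.132 among the control probes). On 5 s replicate 2, 14 coding sequences lay more than 1 from the mean of the other 2 arrays where those agreed within 0.5, 13 of them lower. The other arrays had 0 to 5 such values.

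A gradient of gene dose along the chromosome was tested as a hypothesis at 20 s. A gradient of note was set in advance as an amplitude of the first harmonic above 0.05 on the log2 scale. The amplitude was 0.0333 (permutation of blocks of 20 coding sequences, p = 0.028), under that bound and small beside the runs. The 20 s mean includes replicate 1, where weak ratios were shrunk, so this amplitude may be too low. The test therefore cannot exclude a weak gradient.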
